A study of Homo sapiens with 6 samples.

How the data were processed

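Total RNA of 6 samples of GEN2.2 cells was measured, 3 from untreated cells and 3 from cells given 1 µM ODN2006 for 2 h. Per the labels' protocols RNA was isolated with a column kit and amplified and labelled with a kit for Illumina bead arrays. A table of probe intensity was deposited by the authors, non-normalized per the file headers, on a linear scale and for 47218 probes per array. A detection p-value for each probe and array was deposited beside it, per the file headers. The deposited log2 values of the same arrays were made with limma, per the submitters' processing notes, with no version given and its steps not given in the sources used here. Within each array these log2 values ranked the probes as the raw signals did. Their medians were 4.67 on each untreated array and 4.59 on each ODN2006 array and their lowest values 4.19 and -1.57, so the groups appear to have been normalized separately, and offset and background steps stay unknown. Across probes detected on no array, the deposited values of the groups differed by a median of -0.45, against 0.00 after joint normalization. They were therefore used only as an alternative.

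The raw intensities were corrected for background with normexp, with the negative control distribution inferred from the detection p-values, an offset of 16 was added, and the 6 arrays were quantile-normalized together (neqc in limma 3.58.1, R 4.3.3). A probe was tested if its detection p was under 0.01 on all 3 arrays of at least 1 group, which left 13816 probes. Of all probes, 30107 had 1 gene symbol in the platform annotation, 8 had several and 17103 had none here. Symbols were updated through gene IDs with the RefSeq table of GRCh38.p14, used only for names and gene order. By this route 30068 probes were named, and 39 kept the platform's symbol. The 11106 tested probes with a symbol stood for 8706 genes, each represented by its brightest tested probe. Of 2003 genes with several tested probes, 89 had probes that differed in call.

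Differences were tested with lmFit and eBayes without covariates, two-sided, with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. A gene whose probes were all undetected on the 3 arrays of a group has only a bound there. It is given as at least N-fold, the mean log2 value of the bright group against the mean, per array, of the higher of the lowest detected signal and the gene's own. The text names the 10 largest rises and falls among called genes whose groups do not overlap, up to 4 called members of each fixed list with the largest change or, where none was called, up to 2 of the brightest members, and TLR9, IFNA2, IFNB1, IFNL1, TNF, IL6, CXCL10, CCL4, GAPDH and ACTB. Other genes named were chosen after their values were seen.

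The 25 gene lists, the tests and most alternatives were fixed before the data were examined. They were NF-kB targets, cytokines and chemokines, type I and III interferons, interferon-stimulated genes, immediate early genes, TLR7/9 signalling, plasmacytoid dendritic cell identity, co-stimulation and maturation, feedback regulators, apoptosis regulators, cell cycle, heat shock, unfolded protein and amino acid response, cholesterol synthesis, hypoxia and glycolysis, metallothioneins, cytosolic ribosomal proteins, nuclear respiratory chain, histones, reference genes, and markers of T and NK cells, B cells, monocytes and conventional dendritic cells, stromal cells, and red cells and platelets. The 20 lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01. Camera with an estimated correlation, camera on ranks and fry were run beside it. Calls were also adjusted over the list alone, which for lists not named with such a count in the results added 1 rise for the unfolded protein list and nothing else. For the TLR7/9 list and the hypoxia list the median was below 0 while camera's direction was up. For the unfolded protein list and the ribosomal protein list median and mean were below 0 and camera's direction was up, and none of these lists passed.

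Replicate numbers come from the sample titles. Deviations from the group means of same-numbered arrays correlated at 0.41, 0.35 and 0.46 across the tested probes, and those of all differently numbered arrays below 0. The negative values partly follow from the positive ones, since deviations within a group sum to 0. By the positive values, not by the labels, the numbers appear to pair the samples. The main fit, fixed in advance, ignores this pairing, so some genes that did not pass in it pass with the pairing. The fit with the replicate number as a block was run as an alternative. The other alternatives were no background correction, median scaling, the deposited log2 values, no filter on dim probes, a stricter filter, a trended and robust variance prior, array weights, the mean of a gene's probes, leaving out each array in turn and the list tests named above. A fit with the slide as a block was not run, because the files used here give no slides.

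The fit was tested on simulated data with the real probe means, the real spreads dealt to probes at random and 50 changed probes of each size in each of 10 rounds over 13816 probes. For the comparison of ODN2006 against untreated it recovered 7.80% of simulated log2 changes of 0.5, 64.8% of 1, 97.6% of 2 and 100% of 4, with 4.35% of calls false on average. At an unadjusted camera p under 0.05, a list moved by design was found in 10 of 10 rounds, and a list left still was called in 0. The real list calls were adjusted over 20 lists. Arrays were simulated without the pairing of samples, so the share of false calls may differ in the real fit. Probes were simulated independently, so this does not show how often lists of correlated genes are called falsely. In the real data the estimated correlation ran from -0.039 for feedback regulators to 0.338 for cytokines and chemokines. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.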

Results

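GEN2.2 is a human cell line derived from a leukaemia of plasmacytoid dendritic cells, the immune cells that sense viral and bacterial nucleic acids in endosomes. Transcript levels were measured on 6 Illumina HumanHT-12 v4 bead arrays, 3 hybridised with RNA from untreated cells and 3 with RNA from cells stimulated with 1 µM ODN2006 for 2 h. ODN2006 is a synthetic oligonucleotide with unmethylated CpG motifs and a ligand of Toll-like receptor 9 (TLR9). The comparison asks which transcripts of these cells differ early after stimulation, and no control oligonucleotide was part of it. Between 13454 and 15447 of the 47218 probes were detected per array, and the median raw signal lay between 107 and 121. After joint normalization, arrays of the same group correlated at 0.983 to 0.991 across the tested probes, and arrays of different groups at 0.960 to 0.974. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision.

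Among genes with a symbol, inflammatory chemokine and cytokine genes and the interferon beta gene rose most. CCL3L3, CCL4L1, CCL3 and CCL3L1, which encode chemokines that attract monocytes and lymphocytes, were detected on no untreated array and were at least 390-fold, 233-fold, 259-fold and 240-fold higher after ODN2006. IFNB1, which encodes interferon beta, was at least 110-fold higher, with 4.37 ± 0.03 on untreated and 12.02 ± 0.26 on ODN2006 arrays (mean log2 intensity ± SD, n = 3). The next largest rises were those of CXCL8, a neutrophil chemokine (log2 change 5.49 ± 0.19 SE), PLAU, the urokinase plasminogen activator (5.42 ± 0.14), IL1B (5.37 ± 0.17), the early activation marker CD69 (4.93 ± 0.15) and CCL5 (4.37 ± 0.20). In the limma fit, the adjusted p of these 10 genes lay between 8.81e-12 and 3.50e-08. CCL3, CCL3L1 and CCL3L3, and likewise CCL4L1 and CCL4, are near-identical copies that probes can share, so which copy rose is uncertain. The probe named for CCL4 itself was detected in neither group.

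**Figure D1:**
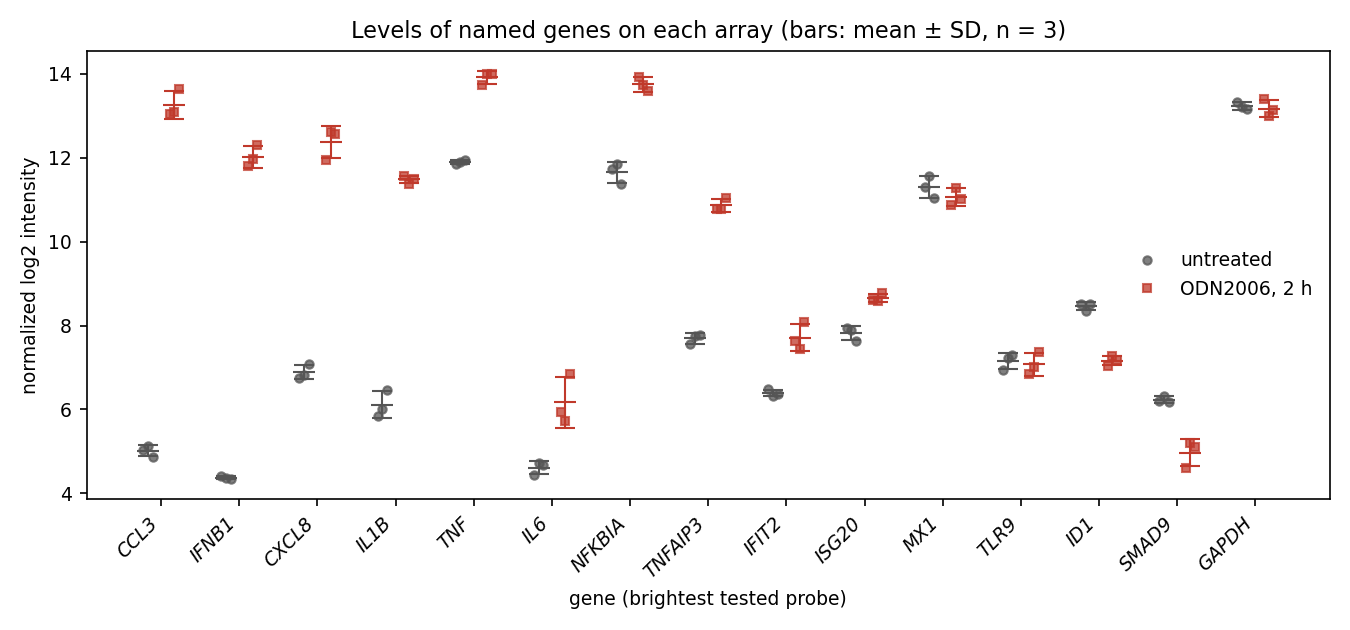
Normalized log2 intensity (vertical axis) of 15 genes on each array, untreated in grey circles and ODN2006 in red squares, with horizontal marks at the mean and bars of 1 SD (n = 3). CCL3 and IFNB1 lay near 5.02 and 4.37 on untreated arrays and at 13.26 and 12.02 after ODN2006, while TLR9, MX1 and GAPDH overlapped between the groups.

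Of 8706 genes tested, 297 rose and 158 fell at an adjusted p under 0.05, the limma test with Benjamini-Hochberg adjustment. At least 2-fold changes were found for 182 rises and 22 falls, 73 genes rose at least 4-fold, and no gene fell by as much (755 genes were lower and 570 higher at an unadjusted p under 0.05). The median log2 change was 1.28 among the rises and -0.72 among the falls. In each of the 297 rises and 158 falls the 3 values of one group all lay above the 3 of the other, as they did in 20.9% of all tested genes, where chance gives 10%. With the replicate number as a block, 405 genes rose and 358 fell, and all 297 rises and 158 falls of the unblocked fit were among them. The count of falls was lower whichever array was left out, fewer samples being part of the cause. It was 97, 51 and 78 without untreated replicate 1, 2 or 3, and 94, 116 and 79 without ODN2006 replicate 1, 2 or 3. The count of rises was then 224 to 268.

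**Figure D2:**
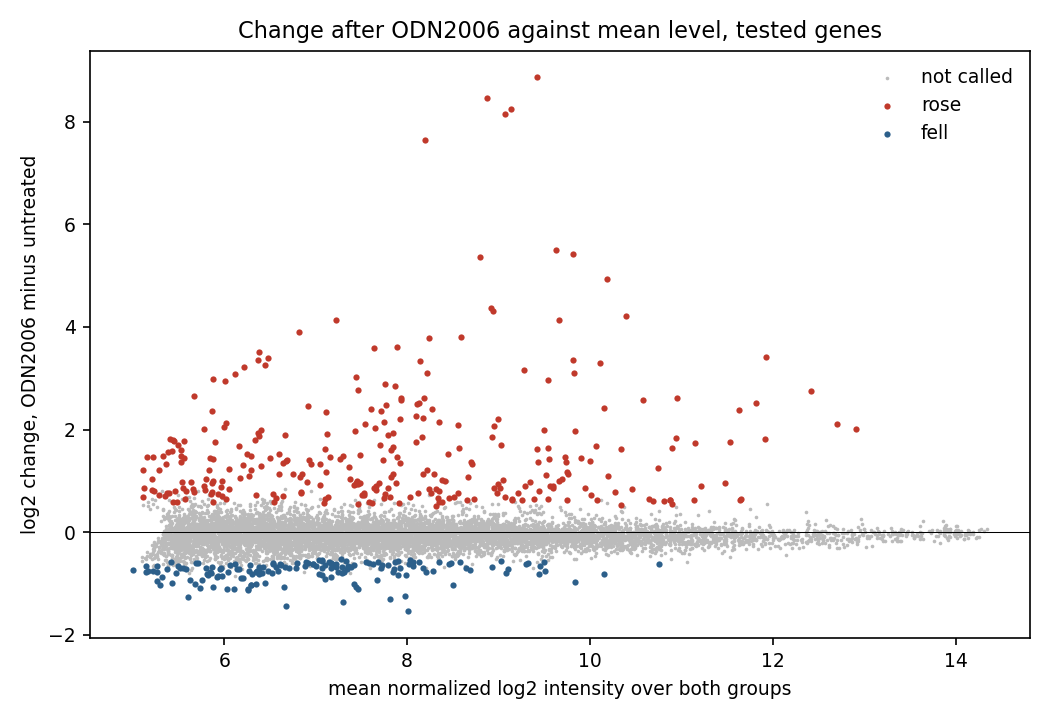
Log2 change, ODN2006 minus untreated (vertical axis), against the mean normalized log2 intensity over both groups (horizontal axis) for the 8706 tested genes, each a point, with the 297 rises in red, the 158 falls in blue and other genes in grey. The largest fall was -1.54, and the points of genes undetected on untreated arrays show differences to background, for which only a bound holds.

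IFNB1 was the only gene of 20 type I and III interferon genes to be tested. Of the others, IFNW1 was detected on 1 ODN2006 array and the remaining 18, IFNA2 and IFNL1 included, on no array. Genes that interferons induce showed no common shift at this time point. Of 38 tested members, 4 rose (4 adjusted over the list alone) and 34 did not pass, with a median log2 change of -0.08 (camera adjusted p = 0.916). The risers were IFIT2 (1.32 ± 0.17 SE), OASL (1.22 ± 0.19), ISG20 (0.84 ± 0.15) and GBP2 (0.81 ± 0.17), all involved in antiviral defence. The call of GBP2 ended without untreated replicate 3 (adjusted p = 0.0748) and without ODN2006 replicate 3 (adjusted p = 0.0774), without background correction (log2 change 0.24, adjusted p = 0.173) and when dim probes were kept in the test (adjusted p = 0.0841). MX1, ISG15 and IFIT1, typical antiviral genes, had log2 changes of -0.24, -0.09 and -0.61 that did not pass, and CXCL10, a chemokine induced by interferons, was detected on 2 ODN2006 arrays only and not tested. With the replicate block, 5 members of the list rose and 1 fell.

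Targets of NF-kB, the transcription factor activated downstream of Toll-like receptors, rose in 24 of 31 tested genes (29 adjusted over the list alone), none fell, and the median log2 change was 1.43 (camera adjusted p = 1.66e-52, and 0.015 with an estimated correlation). With the replicate block as well as an estimated correlation the list did not pass (adjusted p = 0.206), while by fry with the block it did (adjusted p = 0.00782). The largest of these rises after PLAU were those of NFKBIZ, an atypical IkB protein (4.22 ± 0.17 SE, with 1.63 at its other probe), PTGS2, the inducible cyclooxygenase (at least 11.5-fold, undetected when untreated), and TNFAIP2 (at least 7.45-fold, likewise). The bound of PTGS2 holds for its brightest probe only, and its other probe had a log2 change of 2.22. Among cytokine and chemokine genes, 14 of 18 tested genes rose (15 adjusted over the list alone) and none fell (median 2.91, camera adjusted p = 1.41e-43, and 0.0211 with an estimated correlation). Another 19 members on the array were not detected on all arrays of either group and not tested. IL6, CCL1, CCL3, CCL3L1 and CCL4L1 entered the test only through their detection after ODN2006, which favours rises. The near-identical copies CCL3 and CCL3L1 count as separate members. This list did not pass either with the block and an estimated correlation together (adjusted p = 0.206), while by fry with the block it did (adjusted p = 0.00589). TNF was already bright in untreated cells, at 11.90 ± 0.04, and rose to 13.91 ± 0.15 (4.04-fold, adjusted p = 1.82e-06). IL6 was undetected in untreated cells and at least 1.90-fold higher after ODN2006 (adjusted p = 0.00211), a call lost when dim probes were kept in the test (adjusted p = 0.0505). IL10 and IL18, bright at 12.90 and 13.90 when untreated, differed by -0.06 each and did not pass. The highest log2 value on any array was 14.44, so IL18 had little room to rise. The rise of TNF, which ended close to that value, may be understated.

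Immediate early genes, which respond to signals without new protein synthesis, rose in 24 of 33 tested genes (28 adjusted over the list alone, where also 2 fell; median 1.75, camera adjusted p = 6.85e-49, and 0.00135 with an estimated correlation). ATF3 (3.81 ± 0.15 SE), EGR1 (3.78 ± 0.17), TRIB1 (3.61 ± 0.16) and NR4A3 (3.59 ± 0.34) rose most, and MYC was the only member that fell (-0.81). Genes that limit signalling rose in 15 of 20 tested members (17 adjusted over the list alone, where also 1 fell) and none fell (median 1.79, camera adjusted p = 2.40e-35, and 0.00163 with an estimated correlation). They included RGS16 (4.31 ± 0.16) and RGS1 (3.29 ± 0.14), which dampen G protein signalling, TNFAIP3 (3.17 ± 0.15), a deubiquitinase that restrains NF-kB, and the phosphatase gene DUSP5 (3.10 ± 0.15). With the block and an estimated correlation together neither of these lists passed (adjusted p = 0.0666 each), while by fry with the block both did (adjusted p = 0.0015 each). The called lists share members with each other.

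Genes of co-stimulation and dendritic cell maturation rose in 9 of 24 tested members (10 adjusted over the list alone), with CD69, CD83 (3.41 ± 0.15 SE), the T cell co-stimulator TNFSF9 (3.34 ± 0.19) and CD40 (2.50 ± 0.19) ahead. The list passed with the preset correlation (median 0.17, camera adjusted p = 1.70e-11) and not with an estimated correlation (adjusted p = 0.115, and 0.250 with the block as well). By fry with the block it passed (adjusted p = 0.0154). With 1 array left out its median ran from 0.10 to 0.33. The tested antigen presentation genes of that list, HLA-DRA and CD74 among them (0.02 each), did not pass. Apoptosis regulators rose in 6 of 17 genes (7 adjusted over the list alone) and BCL2L2 fell (median 0.16, camera adjusted p = 2.88e-05, and 0.0348 with an estimated correlation). The median of these regulators ran from 0.09 to 0.21 with 1 array left out. With the block and an estimated correlation together this list did not pass (adjusted p = 0.213), while by fry with the block it did (adjusted p = 0.00782). The risers act in opposite ways: PMAIP1 promotes apoptosis (2.62 ± 0.15, with 1.69 at its other probe), CFLAR (1.43 ± 0.17) and MCL1 (0.76 ± 0.17) oppose it, and CDKN1A arrests the cell cycle (1.85 ± 0.16). The call of MCL1 was lost without untreated replicate 1 or 2 or ODN2006 replicate 2 or 3, with adjusted p between 0.0510 and 0.0827, and when dim probes were kept in the test (0.0761).

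The receptor gene TLR9 differed by -0.09 ± 0.17 SE (7.16 ± 0.20 untreated, 7.07 ± 0.28 after ODN2006). In the TLR7/9 signalling list, 2 of 28 genes rose, the kinase gene MAP3K8 (2.59 ± 0.15) and IRAK2 (1.27 ± 0.16), and the list, in which 2 genes also fell adjusted over the list alone, did not shift as a whole (camera adjusted p = 0.762). With the replicate block, 2 genes of that list also fell. Among 30 genes of plasmacytoid dendritic cell identity, the transcription factor gene IRF4 rose (0.93 ± 0.16 SE), DERL3 fell (6.85 ± 0.14 untreated, 5.85 ± 0.45 after ODN2006, mean ± SD), and 28 did not pass (camera adjusted p = 0.815). DERL3 lost its call without untreated replicate 3 (adjusted p = 0.0590) and when dim probes were kept in the test (adjusted p = 0.107). The surface marker CLEC4C differed by 0.00. Another 8 identity genes on the array, LILRA4, PTCRA, BLNK and SERPINF1 among them, were not detected on all arrays of either group and not tested. With the replicate block, 2 of the 30 identity genes fell.

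**Figure D3:**
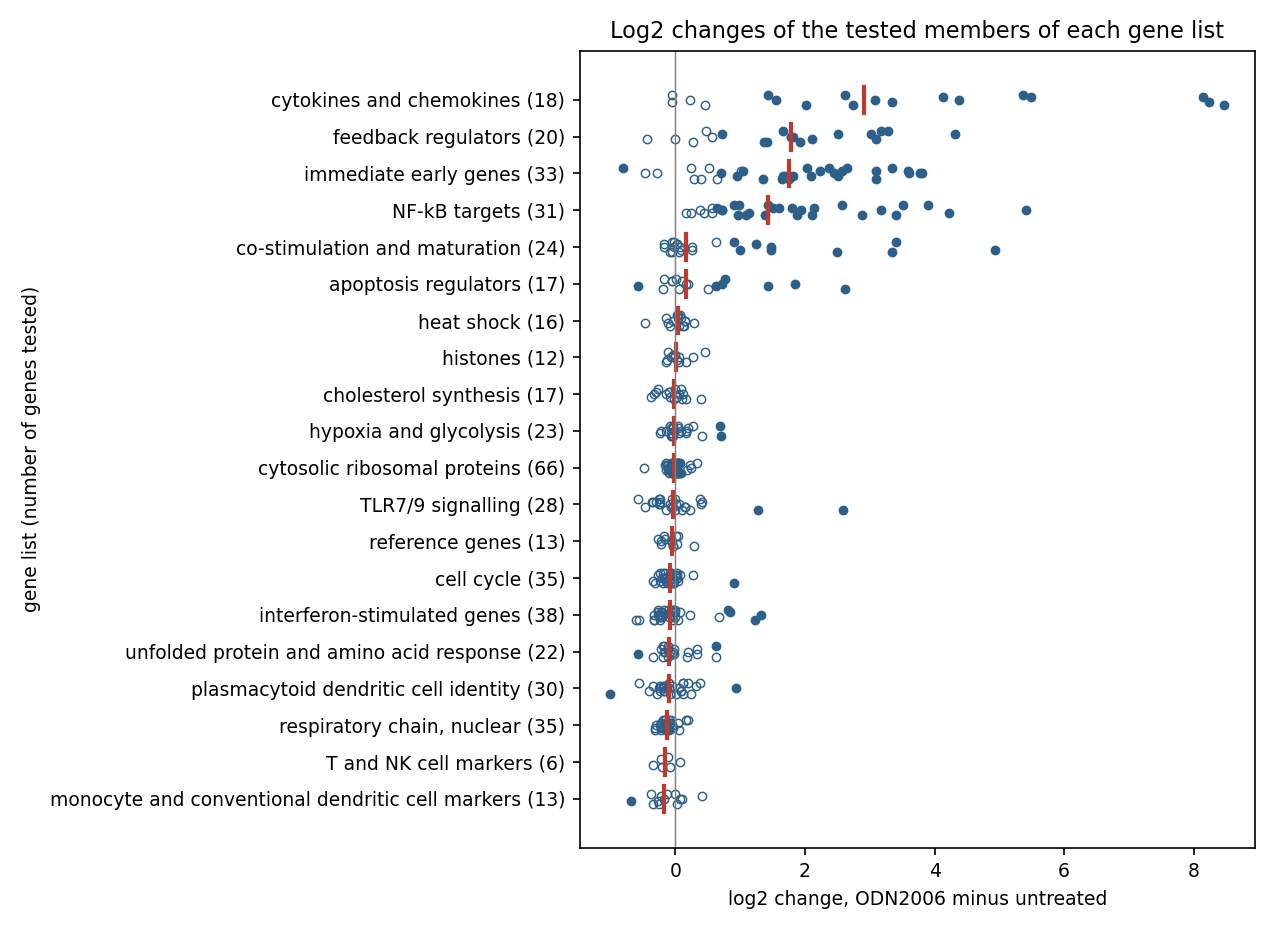
Log2 change, ODN2006 minus untreated (horizontal axis), of each tested member of the 20 gene lists with at least 5 tested genes (vertical axis, number of genes in brackets), with filled points for genes past the adjusted p, open points for the others and red lines at the list's median. Medians ran from -0.18 to 2.91, and 4 lists had a median above 1.

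Lists of general cell functions did not pass the camera test, and fry, which asks whether a list's genes move one way on balance and not whether they differ from other genes, called the same 6 lists as camera. CCND1, the cyclin D1 gene, rose (0.90 ± 0.15 SE) and the other 34 of 35 cell cycle genes did not pass (adjusted p = 0.634). VEGFA (0.71) and PFKFB3 (0.69, with 0.35 at a second probe that did not pass) rose among 23 hypoxia and glycolysis genes (adjusted p = 0.227). ATF5 rose (0.63) and CEBPB fell (-0.57) among 22 genes of the unfolded protein and amino acid response (adjusted p = 0.916). No member passed among 16 heat shock genes (adjusted p = 0.634), 17 cholesterol synthesis genes (0.946), 66 cytosolic ribosomal protein genes (0.874), 35 nuclear genes of the respiratory chain (0.136), 12 histone genes (0.634) or 13 reference genes (0.762). The brightest members of these lists had log2 changes of 0.03 for HSP90AA1 and 0.04 for HSPD1 (another probe had 0.56 and did not pass), -0.14 for HSD17B7 and 0.17 for INSIG1, -0.10 for RPL41 and -0.11 for RPS12, 0.06 for ATP5F1B and -0.10 for COX4I1, and 0.02 for H3-3A and -0.13 for H2AZ1. Among reference genes GAPDH had -0.07 ± 0.15, ACTB -0.03 ± 0.14 and B2M -0.05 ± 0.15. Of 3 tested metallothionein genes none passed, with MT1X at -0.11 and MT1E at -0.17. With the replicate block, 1 heat shock gene and 1 cytosolic ribosomal protein gene fell, and 2 genes of the unfolded protein list rose in place of 1. The calls of ATF5 and CEBPB were lost without any 1 of the 6 arrays and with median scaling, that of VEGFA without any of 4 arrays, those of ATF5 and VEGFA also when dim probes were kept in the test (adjusted p = 0.118 and 0.0562), and that of PFKFB3 without untreated replicate 1 (adjusted p = 0.0513).

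The lists of markers of other cell types that had enough tested genes did not pass. Among 13 tested monocyte and conventional dendritic cell markers CEBPA, a myeloid transcription factor gene, fell (-0.69 ± 0.15 SE, a call lost without any of 4 arrays) and 12 did not pass (camera adjusted p = 0.464). The 6 tested T and NK cell markers did not pass (adjusted p = 0.547), with CD6 at -0.12 and CD5 at 0.08, and of the lists too short to test none of 4 B cell markers passed, with CD79B at -0.21 and CD79A at 0.28, nor any of 3 stromal markers, with TIMP1 at -0.30 and TAGLN at -0.02, and no red cell or platelet marker was detected on all arrays of a group.

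Falls were smaller than rises. The largest were those of ANKRD13D (-1.54 ± 0.16 SE), C12orf76 (-1.44 ± 0.18), the long non-coding RNA LINC01089 (-1.37 ± 0.16), ID1, an inhibitor of DNA binding that BMP signalling induces (-1.29 ± 0.14), SMAD9, a signal transducer of BMP receptors (-1.26 ± 0.17), and FRAT2, which acts in WNT signalling (-1.24 ± 0.16). SNORA57, ZNF526, C2orf68 and PDK4, a kinase that restrains pyruvate oxidation, followed with -1.12, -1.11, -1.10 and -1.10. In the limma fit the adjusted p of these 10 genes lay between 5.52e-05 and 0.00786. PDK4 lost its call without background correction (adjusted p = 0.0559), and SNORA57 (0.0519) and PDK4 (0.0821) when dim probes were kept in the test. SMAD9 was detected on only 1 ODN2006 array, where its group mean of 4.97 lay below the lowest detected signal of any array (5.18). C2orf68 and PDK4 were detected on 2 ODN2006 arrays. The sizes of these falls therefore reach into background and are uncertain.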

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

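Probes without a gene symbol here stood outside the comparisons of genes. Of 2710 such tested probes, 75 rose and 51 fell, and 46 rose and 7 fell at least 2-fold. Their largest log2 change was 9.11, against 8.86 for CCL3L3, the largest rise of a gene with a symbol. Of the 75 probes that rose, 23 were detected on no untreated array, as were 40 of the 297 genes that rose. The comparisons of genes leave this signal aside although the same fit tested these probes. Which transcripts they measure was not analysed here, and no explanation was tested.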

How the results depend on the processing

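Camera with an estimated correlation in the fit with the replicate block was chosen after the data were seen, and every other alternative before, leaving aside fry in that fit. Probe signal over background limits the data: 28.5% to 32.7% of probes were detected per array. Of 76 named genes tested, none of the 54 called turned direction under any alternative, and 13 of the uncalled, near 0, did. Leaving out 1 array left 428 values on their side of the threshold and ended 28 calls, in 8 genes. The other settings left 658 and ended 12, in 9 genes. The replicate block gave 405 rises, 183 of them at least 2-fold, and 358 falls in place of 158, and changed no call of a named gene or, with the preset correlation, of a list. Genes lower after ODN2006 numbered 104 with median scaling and 75 without the filter on dim probes, which tests 20041 genes. Over the leave-one-out fits the falls ranged from 51 to 116, fewer samples being part of the cause, and the rises from 224 to 268. Changes of at least 2-fold numbered 106 without background correction in place of 204, with 105 rises and 1 fall, since background left in the signal shrinks ratios. Falls of at least 2-fold numbered 14 among genes detected on all 6 arrays and 14 with array weights in place of 22, and 14 to 30 with 1 array left out, 14 without untreated replicate 3; the cause was not tested. With an estimated correlation the maturation list lost its call (adjusted p = 0.115). With the replicate block as well, the adjusted p was 0.206 for NF-kB targets and for cytokines, 0.0666 for immediate early genes and for feedback regulators, 0.213 for apoptosis regulators and 0.250 for maturation. The block leaves fewer degrees of freedom, and the cause was not tested further. By fry with the block these lists all passed, with adjusted p between 0.0015 and 0.0154. The respiratory chain list, not called in the main setting, passed as a fall without background correction (median -0.13, adjusted p = 0.0112), without the filter (-0.14, 0.00281) and on ranks (adjusted p = 0.0292), and with 1 array left out its median ran from -0.194 to -0.083 and its adjusted p from 0.0158 to 0.699, passing without untreated replicate 2 and without ODN2006 replicate 1; the cause was not tested.
The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 297 higher, 158 lower and 204 genes changed at least 2-fold, each in 1 of the 10 splits, and the highest of the others gave 0. With the block, the 3 other splits that part all pairs gave 0 as well. Of list calls with the preset correlation the real split gave 6, as many as or fewer than 5 of the 10 splits, itself included, and the highest other gave 7. The other splits still hold unequal numbers of treated arrays, and 3 to 6 of the lists they called were among those of the real split. With an estimated correlation the real split called 5 lists and the others 0. In each other split the groups mix treated and untreated arrays, so any treatment effect widens the spread within groups. Their counts of 0, for genes and for lists, follow from that and lend the real split no support.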

Other observations

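The tests on zinc finger genes, small RNAs, neighbouring genes and the brighter interferon-stimulated genes were chosen only after those patterns were seen. The genes named here were also chosen after their values were seen. Some genes of cell surface receptors outside the fixed lists changed, and no list of such genes was tested. PTGER4, which encodes a prostaglandin E2 receptor, rose by 2.96 ± 0.16 SE on the log2 scale, GPR84 by 2.39 ± 0.16 and GPR183 by 1.65 ± 0.15, while FFAR4 (-1.02 ± 0.14) and the chemokine receptor gene CCR2 (-1.09 ± 0.20) fell. PTGER2, which encodes another receptor of that ligand, was undetected in untreated cells and at least 2.91-fold higher. The microRNA host gene MIR155HG rose by 4.13 ± 0.21, and MIR3142HG, undetected in untreated cells, was at least 7.62-fold higher.

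Several markers of monocytes and conventional dendritic cells were detected on all 6 arrays, treated or not. Of 21 such markers on the array, 13 were tested, and 8 were not detected on all arrays of either group. Untreated cells had 10.60 ± 0.14 for CD14, 11.13 ± 0.13 for CSF1R, 12.46 ± 0.13 for CD1C and 10.19 ± 0.09 for CLEC10A (mean log2 intensity ± SD, n = 3). None of these differed past the threshold after ODN2006.

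IFNB1 rose at least 110-fold while 34 of 38 tested interferon-stimulated genes did not pass. The probes were not near saturation, since the highest log2 value lay 7.31 above the members' median level. Median scaling gave a median log2 change of -0.10 for the list, against a common rise hidden by quantile normalization. Dim signal does not account for the 16 members brighter than the median tested gene, of which 1 rose, with a median log2 change of -0.082 ± 0.070 (standard error). The list's median level lay at percentile 37.8 of tested genes, between the bounds set in advance, so dim signal stays open for the 22 other members, of which 3 rose, with a median of -0.09. A time point too early for secreted interferon to act is a candidate explanation that no other time point here could test.

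Among 92 families of gene symbols with at least 10 tested genes, zinc finger genes named ZNF held more falls than other genes: 15 of 216 fell and 1 rose (6.94% against 1.68%, adjusted one-sided Fisher's exact p = 0.000751, across genes, which are not independent replicates). Their median log2 change was -0.17, against -0.05 for other genes, and it stayed below 0 under each scaling, at -0.09 without background correction and -0.08 without the filter on dim probes. The count of falls was 8 without untreated replicate 2 and 9 without untreated replicate 3, 8 without the filter on dim probes and 24 with the replicate block. The families SNORD (7 of 56, adjusted p = 0.00287) and SNORA (5 of 39, adjusted p = 0.0198) also held more falls by the same Fisher's exact test, and SNORD (8 of 56, adjusted p = 0.0175), IL (10 of 28, 1.29e-06) and MIR (5 of 20, 0.0175) more rises. The ZNF median lay at percentile 0.01 of 10000 random lists matched on mean level, the lowest they can give. Those lists had medians of -0.11 to 0.02, so a like mean level alone did not give the lower ZNF values. The family was picked for its falls and random lists ignore links between its genes, so the percentile is no measure of chance. With median scaling 11 fell (one-sided Fisher's exact p = 5.01e-05), against quantile normalization as the whole cause. Short-lived transcripts that fall when transcription is redirected may be involved, which was not tested.

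Small RNAs moved apart. Of 21 tested small RNAs transcribed from their own promoters, 15 rose and none fell, with a median log2 change of 1.22. The risers include U1, U4, U5 and U11 small nuclear RNAs, the U3 genes SNORD3A, SNORD3C and SNORD3D (1.62 to 1.98) and RPPH1 (1.32). RNU6-1 (-0.08), RNU6ATAC (0.22), RN7SK (-0.07), RN7SL1 (-0.03), RNY1 (-0.18) and RNY3 (0.04) did not pass, so the whole class did not share the rise. Many of the risers are near-identical copies, and the 15 fall into 8 name families. Of 100 other small nucleolar and Cajal body RNAs, most of them hosted in introns, 8 rose and 12 fell, with a median of -0.11 ± 0.06 (standard error), so higher recovery of all short RNAs after ODN2006 would have to have missed these. In place of 12 falls there was 1 without untreated replicate 2, and there were 2 without untreated replicate 3, 2 without ODN2006 replicate 1, 6 without ODN2006 replicate 2 and 4 without ODN2006 replicate 3, and 5 with median scaling, 4 without background correction, 2 without the filter on dim probes and 18 with the block. In place of 8 rises there were 5 without untreated replicate 1, without ODN2006 replicate 2 and without background correction, 4 among genes detected on all 6 arrays and 12 with the block. The median of the first class lay at percentile 99.99 of 10000 random lists matched on mean level, whose medians ran from -0.23 to 0.14. A like mean level alone therefore did not give the rise. The class was picked after its rise was seen and holds near-identical copies, so the percentile is no measure of chance. The median of this class was 0.70 without background correction and 1.21 with median scaling. The labelling kit primes on poly(A), so a change in processing or tailing rather than in amount may be measured and stays untested.

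Some called rises lay next to each other in the genome, such as KDM6B with TMEM88, TLCD1 with NEK8 and NEK8 with TRAF4, which prompted a test of positions. Without these 5 genes, both genes rose in 13 of 7675 neighbouring pairs of tested genes (overlaps, small RNAs and pairs alike in name left out), against a mean of 7.97 and a highest count of 19 in 10000 shuffles within chromosomes (one-sided permutation p = 0.0532, across genes). Positions shared by chance were therefore not excluded. Neighbours were consecutive tested genes at any distance, so the test cannot judge genes that lie close together. With the 5 genes the count was 16 of 7681 against a mean of 8.31 (permutation p = 0.0071, which partly restates what prompted the test), and for falls 2 against a mean of 2.22 (permutation p = 0.653).

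ID1, ID3 and SMAD9 fell (-1.29, -0.97 and -1.26), SMAD9 being detected on only 1 ODN2006 array. A common fall of genes that BMP signalling induces was a hypothesis. Of 6 other tested members of a list of 17 such genes, none fell, ID2 rose (0.56, with another probe that did not pass), and their median was -0.10 ± 0.16 (standard error). That does not separate a weak common fall from none, so the hypothesis stays open.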
